A study of Mus musculus with 29 samples.

How the data were processed

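The data are 29 Agilent 2-colour whole-genome arrays of mouse liver RNA, 1 per animal, in 4 diet groups. Per the labels' protocols, 1000 ng of total RNA per liver was split and amplified with Cy5 and with Cy3. The Cy3 products were pooled into a common reference, and each Cy5 product was hybridised against it. No dyes were swapped. A dye effect that is equal on all arrays cancels between groups, while one that differs between arrays does not. Per the labels, 1 high-fat and 1 rosiglitazone array were excluded by the authors before normalization. Each sample's group and replicate number came from its label. The replicates are livers of separate mice.

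Per the file headers, the scanner files hold the linear intensity of each spot in Cy5 and Cy3 with its local background, as extracted by Agilent Feature Extraction 10.5.1.1, with no normalization between arrays. The authors also deposited a table of log2 normalized values with 25806 probes and a median of 9.03 in every column. Set against the scanner files, each of its 29 columns followed its own array's log2 Cy5 intensity best (r from 0.990 to 0.999), and after centring each probe r with the ratios used here was 0.859. The table is thus on the log2 scale and follows the Cy5 channel, with no ratio taken; how it was normalized is not given in the sources used here. It served as an alternative.

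Mean spot intensities were background-corrected with normexp (offset 50) on the local background and normalized within each array by loess with limma 3.58.1 in R 4.3.3 and data.table (version 1.17.8). Control spots had no weight in the loess curve and, with spots marked as outliers, were left out. Spots of a probe were averaged. A probe was kept if it was well above background in Cy5 on at least 6 arrays and had a value on at least 20. Of 39429 probes, 23932 passed. Names came from the accession for 26412 probes, a symbol for 3854 and a synonym for 735, matched to genes of the assembly GRCm38.p6, which served for names only, and 8428 probes keep the name in the file. Each gene was represented by its probe of highest mean intensity. That gave 19465 genes, of which 3775 had several probes and 3537 keep the name in the file. No named gene had another probe past the threshold in the opposite direction. Probe positions are those in the files, whose header names the build mm9. A named gene with values on few arrays is described as such, and probes of gene families (Cyp4a, Cyp2a, Cyp2c, Fabp5) can bind the transcripts of relatives.

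A linear model with 4 group means was fitted to all 29 arrays with limma (lmFit and eBayes), and the 4 groups share 1 estimate of the spread per gene. The comparisons were cHF+PC, cHF+R and cHF+PC+R against cHF, cHF+PC+R against cHF+R and against cHF+PC, the interaction, and both effects averaged over the other factor. All tests are two-sided. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The words rose and fell are used of genes past it, and errors are standard errors of the fit. The arrays lay on 8 slides with at most 1 array of a group per slide, so the slide was run as a block and changes were also taken within slides.

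The comparisons, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. Per comparison, the rule names the 10 rising and 10 falling genes with the largest changes past the threshold, up to 4 members per list with the smallest adjusted p, the 5 with the smallest p where fewer than 5 pass, and a fixed set of anchor genes of lipid metabolism. Results of some single genes under this rule are not reported here, and those genes were left out of the search for livers far from their group. The 30 lists hold 422 genes, none on more than 1 list (0 shared). They cover lipid, sterol, bile acid, xenobiotic, glucose and stress pathways, liver processes such as the clock and the acute phase, and markers of the cell types a liver sample can hold. Each list was tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated per list and with fry, each adjusted over the 30 lists. Counts of members are given over all genes and adjusted over the list alone.

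The tests were checked on simulated data with independent noise per gene and known changes in genes drawn at random. For cHF+PC against cHF, 74.6% of changes of 0.3, 95.5% of 0.6 and 100% of 1 on the log2 scale were recovered, while 14 unchanged genes also passed. Alternatives were no background subtraction, Feature Extraction's own processed signals, median centring in place of loess, loess followed by scaling between arrays, quantile-normalized Cy5 alone, the deposited value table, other filters, the mean of a gene's probes, the slide or the replicate number as a block, only the compared groups in the fit, array weights, an intensity trend and each array left out in turn. Other splits of the arrays were drawn 100 times per comparison. At the preset correlation such splits passed a median of 4 to 9 of the 30 lists. The camera p-values at that setting therefore overstate the evidence for a list.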

Results

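Livers of 29 male C57BL/6N mice were profiled on 2-colour oligonucleotide arrays, with 1 array per liver. All mice were 3 months old at the start and ate a high-fat diet based on corn oil (cHF) for 7 weeks. The diet was given alone, with omega-3 phospholipids (cHF+PC), with a low dose of rosiglitazone (cHF+R) or with both (cHF+PC+R). The phospholipids carried the marine fatty acids EPA and DHA and replaced about 7% of the dietary lipid. Rosiglitazone is an agonist of the nuclear receptor PPAR-gamma and was developed as an insulin sensitiser. The groups held 7 cHF, 6 cHF+R, 8 cHF+PC and 8 cHF+PC+R livers. Each value is the log2 ratio of a liver (Cy5) to a pool of all samples (Cy3), so a change is a difference of such ratios between groups. Of 43020 spots that were not controls, 80.8% were well above background in Cy5 on cHF replicate 4 and between 55.0% and 62.5% on the others, and the number of arrays limits the precision. Over 39429 probes, the lowest correlation between a pair of arrays was r = -0.329 (cHF+PC replicate 6 with cHF+R replicate 5). The median was 0.363 within groups and 0.172 between groups. Since the labels state the dyes and the reference held every group, opposite ratios can occur and the direction was kept. In all, 19465 genes were tested.

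The first comparison, cHF+PC with cHF, asked what the phospholipids changed in the liver. Enzymes of cholesterol synthesis fell almost as a block. Of 19 measured enzymes, 18 fell (18 adjusted over the list alone), with a median log2 change of -0.75. The median was lower in 7 of the 7 slides that carried both groups, from -1.26 to -0.35 within slides, and was -0.76 with the slide as a block. Sqle, squalene epoxidase, fell 4.78-fold, a log2 change of -2.26 ± 0.425 (SE; adjusted p = 0.00222). Idi1, which isomerises isopentenyl diphosphate, fell by 1.57 ± 0.295. Fdps, farnesyl diphosphate synthase, fell by 1.47 ± 0.211, and Pmvk, phosphomevalonate kinase, fell by 1.12. The list stood below the other genes by camera (adjusted p = 4.37e-26) and also with an estimated correlation (adjusted p = 0.0405). The probe for Sqle lies on chromosome 15, from 59162688 to 59162747 in mm9.

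Fatty acid synthesis was lower as well in cHF+PC than in cHF. Of 16 measured genes, 8 fell (11 adjusted over the list alone) and none rose, with a median of -0.71, from -1.02 to -0.14 within 7 slides and -0.64 with the slide as a block. The list passed camera (adjusted p = 5.84e-12) but not with an estimated correlation (adjusted p = 0.076). Acacb, an acetyl-CoA carboxylase, fell by 1.43 ± 0.249, and Fasn, the fatty acid synthase, fell by 1.21 ± 0.272 (adjusted p = 0.0087). Elovl5, an elongase, fell by 1.14, and Acly, ATP citrate lyase, fell by 0.98. The other probes of Acacb and Acly had smaller changes of -0.47 and -0.21 and did not pass. The desaturase Scd1 had a log2 change of -0.90 ± 0.448 (adjusted p = 0.283), and Srebf1, which encodes a transcription factor of lipogenesis, one of 0.07 ± 0.155 (adjusted p = 0.875). Apoa4, an apolipoprotein, fell by 1.84 ± 0.188 in 7 of 7 slides. It led the list of triglyceride synthesis and VLDL assembly, of which 2 of 12 fell (2 adjusted over the list alone). That list had a median of -0.17 (camera adjusted p = 0.0374), lost with an estimated correlation (adjusted p = 0.544). It was also lost without cHF replicate 4 (0.076) or cHF+PC replicate 2 (0.0692).

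Some genes of fatty acid oxidation and of xenobiotic metabolism rose with phospholipids. Of 21 genes of peroxisomal and microsomal oxidation, 6 rose (8 adjusted over the list alone), with a median of 0.23, from 0.06 to 0.53 within 7 slides. The camera call (adjusted p = 1.13e-09) was lost with an estimated correlation (adjusted p = 0.174). The fatty acid omega-hydroxylases Cyp4a10 and Cyp4a31 rose by 1.77 ± 0.151 and 1.65 ± 0.129, and Ehhadh, a bifunctional peroxisomal enzyme, rose by 1.11. Acot1, an acyl-CoA thioesterase, rose by 0.72. Cyp4a14 had values on only 2 of the 7 cHF arrays, and its change of 2.69 ± 0.563 (adjusted p = 0.00907) was lost without cHF replicate 1 (adjusted p = 0.236). Of 19 genes of mitochondrial oxidation and ketogenesis, 3 rose (8 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 7.65e-05). With an estimated correlation the adjusted p was 0.537. Eci2, an enoyl-CoA isomerase, rose by 0.40, and the carnitine transferase Cpt1a had a change of 0.05 ± 0.082 (adjusted p = 0.828). In xenobiotic metabolism, 5 of 21 genes rose (11 adjusted over the list alone), with a median of 0.39, higher in 6 of 7 slides. This call held with an estimated correlation (adjusted p = 8.15e-09 and 0.0215). Cyp3a11 rose by 0.94, Abcc3, an efflux transporter, by 0.49, Nr1i2, the pregnane X receptor, by 0.46, and Cyp3a13 by 0.44.

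Genes of bile acid handling moved both ways in cHF+PC, with 2 of 16 higher and 2 lower (4 and 2 adjusted over the list alone) and a camera adjusted p = 0.457. Abcg5 and Abcg8, which form the transporter of sterols into bile, rose by 0.90 ± 0.139 and 0.74 ± 0.117. Cyp8b1, which makes cholic acid, fell by 1.64 ± 0.354. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.13 ± 0.297 (adjusted p = 0.0278). That last call was lost without cHF replicate 4 (0.0686), 5 (0.0664) or 6 (0.0518), or without cHF+PC replicate 2 (0.0607) or 4 (0.0616). Pparg fell by 0.74 ± 0.182 (adjusted p = 0.0183) and was the only 1 of 16 PPAR-gamma targets and lipid droplet genes to pass (2 adjusted over the list alone). The lipid droplet gene Cidec had a change of -1.36 ± 0.457 (adjusted p = 0.0901). The list's median was -0.24 (camera adjusted p = 0.0156), lost with an estimated correlation (adjusted p = 0.635).

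Across all genes, 766 passed in cHF+PC against cHF, 351 higher and 415 lower, of which 46 and 90 changed at least 1.5-fold. The largest rise was in Krt23, a keratin, by 3.58 ± 0.263 (adjusted p = 9.09e-10), in 7 of 7 slides; its probe lies on chromosome 11, from 99339393 to 99339452 in mm9. Igfbp2, which binds insulin-like growth factors, rose by 1.17 ± 0.155. Hsd17b6, a steroid dehydrogenase, rose by 1.15 ± 0.198, Trib3, a pseudokinase of the stress response, by 1.27 ± 0.268, and Cyp2a4 by 1.25 ± 0.302. Csad, which acts in taurine synthesis, fell by 1.58 ± 0.288, and Dntt fell by 1.40 ± 0.159. The count was 439 without cHF+PC replicate 4, 486 without cHF replicate 5 and 601 with the slide as a block. With array weights 1223 genes passed and 56.6% of them were higher, against 45.8%, and only 10 passed with median centring in place of loess and 255 with scaling between arrays.

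**Figure D1:**
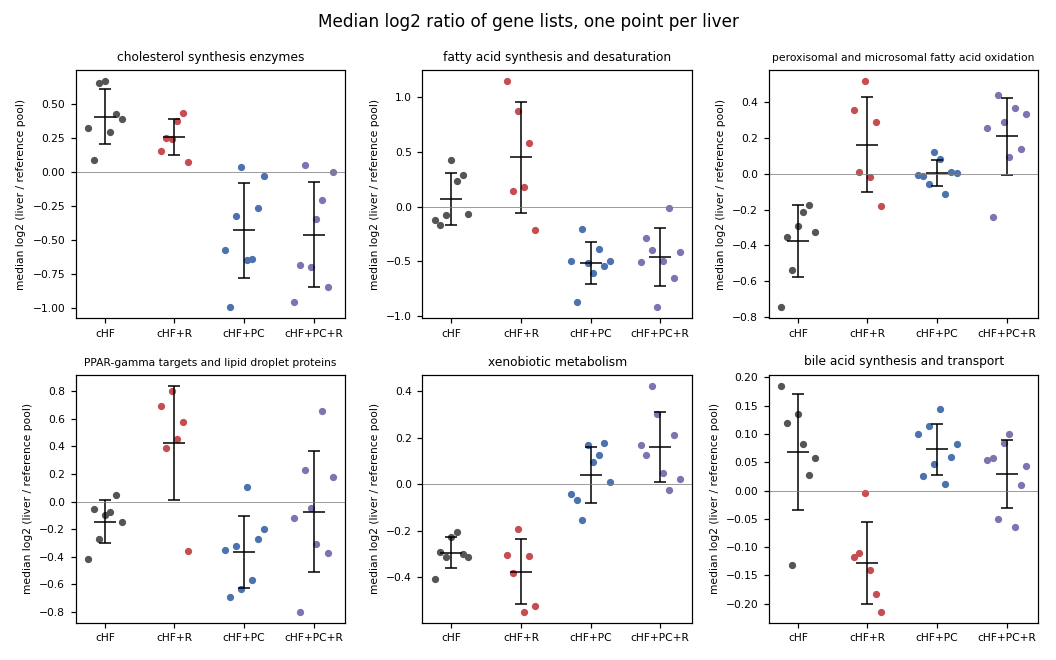
Median log2 ratio of liver to reference pool over the genes of 6 lists, 1 point per liver, by group on the x axis, with the group mean and SD. The cholesterol synthesis enzymes sat lower in cHF+PC and cHF+PC+R than in cHF, with median changes of -0.75 and -0.84, and bile acid genes sat lowest in cHF+R.

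The second comparison, cHF+R with cHF, asked what low-dose rosiglitazone changed. Genes of lipid storage and lipid uptake were among those that rose. Cfd, adipsin, a protease abundant in adipocytes, rose by 4.51 ± 0.835 or 22.8-fold (adjusted p = 0.00148), in 5 of 5 slides; its probe lies on chromosome 10, from 79355302 to 79355361 in mm9. The lipid droplet genes Cidec and Plin4 rose by 2.48 ± 0.491 (adjusted p = 0.0027) and 2.32 ± 0.383 (adjusted p = 0.000369). The fatty acid transporter Cd36 rose by 1.61 ± 0.241, Lpl, lipoprotein lipase, by 1.53, and the fatty acid binding protein Fabp5 by 2.03 ± 0.262, with its near copy Fabp5l2 at 2.25 ± 0.269. Of 16 PPAR-gamma targets and lipid droplet genes, 6 rose (9 adjusted over the list alone), with a median of 0.57, higher in 4 of 5 slides and 0.64 with the slide as a block. The camera call (adjusted p = 2.91e-08) was lost with an estimated correlation (adjusted p = 0.227). Pltp, the phospholipid transfer protein, rose by 0.88. Fabp4 rose by 1.27 ± 0.307 (adjusted p = 0.0167), a call lost without cHF+R replicate 1 (0.0605) or 3 (0.0557). Pparg itself had a change of -0.33 ± 0.196 (adjusted p = 0.45).

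Peroxisomal and microsomal oxidation rose with rosiglitazone in 10 of 21 genes (15 adjusted over the list alone), with a median of 0.58, from 0.11 to 1.29 within 5 slides. This call held with an estimated correlation (adjusted p = 4.91e-17 and 0.0442). Acaa1b, a peroxisomal thiolase, rose by 1.18, Cyp4a10 by 1.15, Ehhadh by 0.97 and Cyp4a31 by 0.96. In mitochondrial oxidation 2 of 19 genes rose (3 rose and 3 fell adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.92). Acadm, the medium-chain acyl-CoA dehydrogenase, rose by 0.65, and Cpt1a had a change of -0.31 ± 0.088 (adjusted p = 0.0503). In fatty acid synthesis 1 of 16 genes rose (6 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00237), lost with an estimated correlation (adjusted p = 0.494). That gene was Scd1, which rose by 1.86 ± 0.482 (adjusted p = 0.0262). The Scd1 call was lost without cHF replicate 1 (0.054), 2 (0.0653) or 3 (0.0631), or without cHF+R replicate 1 (0.0848), 3 (0.0804) or 5 (0.0531). Fasn had a change of 0.31 ± 0.292 (adjusted p = 0.678). Of 19 cholesterol synthesis enzymes 1 fell (1 adjusted over the list alone), Acat2 at -0.32. Their median of -0.20 turned to 0.10 with median centring and 0.11 with scaling between arrays, and the camera call (adjusted p = 0.0198) was lost with an estimated correlation (adjusted p = 0.74) and without cHF replicate 3 (0.0602) or 4 (0.0656) or cHF+R replicate 6 (0.0929). In triglyceride synthesis and VLDL assembly 1 of 12 genes fell (2 rose and 2 fell adjusted over the list alone), Apoc3 at -0.39, whose other probe had a change of 0.14.

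Several cytochromes of the Cyp2c family fell with rosiglitazone. Cyp2c54, Cyp2c50, Cyp2c37, Cyp2c38 and Cyp2c39 changed by -1.41 ± 0.2, -1.20 ± 0.163, -1.18 ± 0.157, -1.17 ± 0.214 and -0.98 ± 0.154, each lower in 5 of 5 slides, and probes of such close relatives can bind each other's transcripts. The other probe of Cyp2c38 had a change of 0.07. In xenobiotic metabolism as a whole 2 of 21 genes fell (1 rose and 4 fell adjusted over the list alone), with a camera adjusted p = 0.203. Of 16 bile acid genes, 2 fell (6 adjusted over the list alone), with a median of -0.18, lower in 5 of 5 slides, which turned to 0.10 with median centring. The camera call held with an estimated correlation (adjusted p = 2.75e-05 and 0.00335) but was lost with median centring (0.231). Akr1d1, a steroid reductase of bile acid synthesis, fell by 0.62. Cyp7a1 had a change of 0.63 ± 0.319 (adjusted p = 0.358). Mfsd2a, a carrier of lysophosphatidylcholine, fell by 1.81 ± 0.41. Slc13a3, a dicarboxylate carrier, fell by 1.38 ± 0.139, and H2-Q1, a class I histocompatibility gene, fell by 1.02 ± 0.158. Male-biased liver genes had a median of -0.23 with 2 of 10 lower (4 adjusted over the list alone), led by Cyp2d9 at -0.65. The median turned to 0.08 with median centring, and the camera call (adjusted p = 0.00436) was lost without cHF+R replicate 1 (0.114) and with an estimated correlation (adjusted p = 0.494).

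Across all genes, 606 passed in cHF+R against cHF, 391 higher and 215 lower, of which 113 and 24 changed at least 1.5-fold. Gprc5b, an orphan receptor, rose by 2.81 ± 0.308 and Serpinb1a, a protease inhibitor, by 2.13 ± 0.337. The count was 584 with the slide as a block and 445 without cHF+R replicate 1, but only 82 with median centring and 70 with scaling between arrays. The share of higher calls was 64.5% but 39.4% of 599 in the deposited value table, 93.9% with median centring, where the median change of all genes was 0.153 (0.0137 with loess), and 85.7% with scaling between arrays. Hepatocyte markers sat lower in cHF+R, with a median of -0.15 and 0 of 11 past the threshold (1 fell adjusted over the list alone). By limma, hepatocyte genes therefore gave no single call, while camera passed (adjusted p = 0.00394), lost with an estimated correlation (adjusted p = 0.359), and the median turned to 0.22 with median centring. The adipocyte markers Adipoq, Plin1 and Lep were near background in every group and were left out by the filter on dim probes. Of the 4 measured adipocyte markers, Cfd and Retn rose (2 adjusted over the list alone), Retn by 0.66, a call lost without any 1 of 19 arrays (highest adjusted p = 0.133, without cHF+R replicate 1). The list had a camera adjusted p = 0.0267, lost with an estimated correlation (adjusted p = 0.474) and without cHF+R replicate 3 (0.0694).

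**Figure D2:**
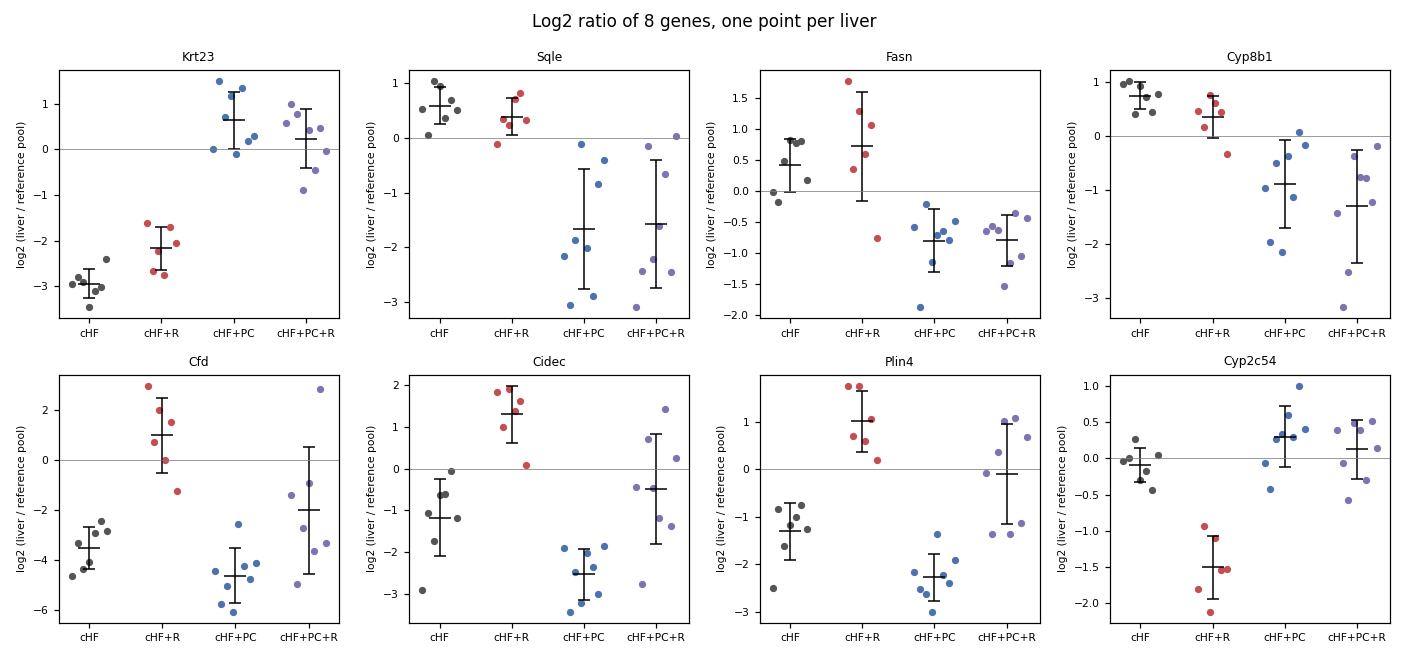
Log2 ratio of liver to reference pool for 8 genes, 1 point per liver, by group on the x axis, with the group mean and SD. Cfd had no value in cHF+PC+R replicate 8. Krt23 was higher in both phospholipid groups, by 3.58 in cHF+PC over cHF and 2.40 in cHF+PC+R over cHF+R, and Cfd was highest in cHF+R.

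The third comparison set livers given both supplements against cHF. Cholesterol synthesis fell in 18 of 19 enzymes (18 adjusted over the list alone), with a median of -0.84, from -1.24 to -0.33 within 7 slides (camera adjusted p = 1.07e-22, and 0.047 with an estimated correlation). Sqle fell by 2.16 ± 0.425, Idi1 fell by 1.63 ± 0.305 and Fdps fell by 1.43. Peroxisomal and microsomal oxidation rose in 13 of 21 genes (15 rose and 1 fell adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.35e-15, and 0.047 with an estimated correlation). Cyp4a10 rose by 2.16 ± 0.151, Cyp4a31 by 1.95 ± 0.129, Ehhadh by 1.41 and Acot1 by 1.27. Xenobiotic metabolism rose in 10 of 21 genes (11 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 4.96e-09, and 0.0176 with an estimated correlation). Cyp3a11 rose by 0.93, Cyp2c55 by 0.88, Abcc3 by 0.73 and Nr1i2 by 0.60, and among other cytochromes Cyp2b10 rose by 1.70 ± 0.402. Fatty acid synthesis fell in 7 of 16 genes (9 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 7.4e-07), lost with an estimated correlation (adjusted p = 0.323). Fasn fell by 1.21 ± 0.272 and Acly fell by 1.06 (-0.30 at its other probe). Mitochondrial oxidation rose in 3 of 19 genes (6 adjusted over the list alone; camera adjusted p = 0.00602, and 0.686 with an estimated correlation), with Acadm up by 0.51. In triglyceride synthesis and VLDL assembly 3 of 12 genes fell (1 rose and 3 fell adjusted over the list alone), with a median of -0.06 that turned to 0.04 with median centring. That camera call (adjusted p = 0.0278, and 0.642 with an estimated correlation) was lost without cHF replicate 4 (0.0546). Of 9 antioxidant and metallothionein genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.0399, and 0.642 with an estimated correlation), a list call lost without any 1 of 5 arrays (highest 0.0993, without cHF replicate 1).

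Lipid droplet and PPAR-gamma genes stood both ways in cHF+PC+R against cHF, with 3 of 16 higher and 2 lower (3 and 2 adjusted over the list alone) and a camera adjusted p = 0.628. Lpl rose by 1.59 ± 0.201 and Cd36 by 0.84 ± 0.224, while Pparg fell by 0.78 ± 0.182. Bile acid genes did likewise, with 2 of 16 higher and 3 lower (3 and 3 adjusted over the list alone) and a camera adjusted p = 0.881. Abcg5 rose by 1.00 and Abcg8 by 0.89, Cyp8b1 fell by 2.05 ± 0.354 and Cyp7a1 fell by 1.48 ± 0.297 (adjusted p = 0.00185). Krt23 rose by 3.18 ± 0.263 and Gprc5b by 2.00 ± 0.286. Apoa4 fell by 2.10 ± 0.188, Aqp8, a water channel, fell by 1.63 ± 0.286, and Dntt fell by 1.64 ± 0.159. In all 1849 genes passed, 920 higher and 929 lower, and 1639 with the slide as a block, but only 77 with median centring and 144 with scaling between arrays. Male-biased liver genes had a median of -0.27 (camera adjusted p = 0.0487, and 0.686 with an estimated correlation), lost without any 1 of 11 arrays (highest 0.132, without cHF replicate 1). The share of higher calls was 49.8% but 30.5% in the deposited value table.

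The fourth comparison, cHF+PC+R with cHF+R, gave the phospholipid effect in livers that received rosiglitazone. It shares the cHF+R livers with the second comparison, so a chance deviation of that group would give opposite changes in both. Fatty acid synthesis fell in 12 of 16 genes (13 adjusted over the list alone), with a median of -0.99, lower in 6 of 6 slides. This call held with an estimated correlation (adjusted p = 2.08e-14 and 0.0376). Me1, malic enzyme, fell by 1.71 ± 0.293, Acacb fell by 1.58, Fasn fell by 1.51 ± 0.283 and Acly fell by 1.19 (-0.34 at its other probe). Cholesterol synthesis fell in 13 of 19 enzymes (18 fell and 1 rose adjusted over the list alone), with a median of -0.74, from -1.28 to -0.12 within 6 slides. Its camera call (adjusted p = 2.08e-14) was lost with an estimated correlation (adjusted p = 0.136). Sqle fell by 1.96 ± 0.444, Fdps fell by 1.42 and Dhcr7, a sterol reductase, fell by 0.81. Xenobiotic metabolism rose in 10 of 21 genes (17 adjusted over the list alone), with a median of 0.54, higher in 6 of 6 slides, and held with an estimated correlation (adjusted p = 1.09e-13 and 0.00149). Cyp2c37 and Cyp3a11 rose by 1.35 ± 0.153 and 1.30 ± 0.142, Cyp2c54 by 1.63 ± 0.194 and Cyp2c38 by 1.54 ± 0.207, again with close relatives among their probes, and the other probe of Cyp2c38 had a change of -0.002.

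Bile acid genes rose in 5 of 16 cases and fell in 2 (9 and 2 adjusted over the list alone) in cHF+PC+R over cHF+R. Their median of 0.22 turned to -0.02 with median centring, and it was 0.04 in cHF+PC over cHF and -0.18 in cHF+R over cHF. The camera call held with an estimated correlation (adjusted p = 0.000492 and 0.0111) but was lost with median centring (0.462). Abcg5 rose by 1.19, Abcg8 by 1.06 and Akr1d1 by 0.57, and Cyp7a1 fell by 2.11 ± 0.31 (adjusted p = 8.19e-05). PPAR-gamma targets and lipid droplet genes fell in 4 of 16 cases (10 adjusted over the list alone), with a median of -0.57, lower in 5 of 6 slides. The camera call (adjusted p = 1.37e-05) was lost with an estimated correlation (adjusted p = 0.217). Pltp fell by 0.85 and Fabp5l2 fell by 1.81 ± 0.261. Cidec fell by 1.78 ± 0.477 (adjusted p = 0.0206), a call lost without cHF+R replicate 1 (0.0602). Cfd, with values on 7 of the 8 cHF+PC+R arrays, fell by 3.01 ± 0.835 (adjusted p = 0.0266). This call was lost without cHF+R replicate 1 (0.0865), 3 (0.0576) or 5 (0.0556) or cHF+PC+R replicate 2 (0.0599), 5 (0.0578) or 7 (0.0556). Of 12 genes of triglyceride synthesis and VLDL assembly 4 fell (6 adjusted over the list alone), led by Apoa4 at -1.49 and Gpam, an acyltransferase, at -0.69. That camera call (adjusted p = 0.00351) was lost with an estimated correlation (adjusted p = 0.217).

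Krt23 rose by 2.40 ± 0.275 in cHF+PC+R over cHF+R, Igfbp2 by 1.37 ± 0.161 and Cyp2a4 by 1.70 ± 0.315, each in 6 of 6 slides. Hsd17b6 rose by 1.36 ± 0.206 and Csad fell by 1.78 ± 0.341. Mitochondrial oxidation had 5 of 19 genes higher and 1 lower (5 and 1 adjusted over the list alone), and Pdk4, a kinase that restrains pyruvate oxidation, fell by 1.09 ± 0.274. Its median of 0.12 turned to -0.10 with median centring, and its camera call (adjusted p = 0.00382) was lost without cHF+R replicate 6 (0.136) and with an estimated correlation (adjusted p = 0.551). Peroxisomal and microsomal oxidation had 3 of 21 genes higher (4 higher and 2 lower adjusted over the list alone) and a camera adjusted p = 0.131, with Cyp4a10 up by 1.01. Hepatocyte markers rose in 2 of 11 cases (5 rose and 1 fell adjusted over the list alone), with a median of 0.21 that turned to -0.04 with median centring, and a camera call (adjusted p = 0.00415) lost with an estimated correlation (adjusted p = 0.217). Of the 4 adipocyte markers 2 fell (2 adjusted over the list alone), with a camera adjusted p = 0.00771, lost with an estimated correlation (adjusted p = 0.217). Cell cycle genes fell in 3 of 14 cases (3 adjusted over the list alone), with Rrm2, a ribonucleotide reductase, at -0.72 (camera adjusted p = 0.00115, and 0.484 with an estimated correlation). Circadian clock genes rose in 2 of 13 cases (2 adjusted over the list alone), with a median of 0.34, higher in 5 of 6 slides. Not all members moved up, with Arntl at -0.551, Nfil3 at -0.391 and Clock at -0.066, none past the limma threshold. The camera call of the clock list (adjusted p = 0.0253) was lost with an estimated correlation (adjusted p = 0.136), with scaling between arrays (0.0559) and without cHF+R replicate 6 (0.0822). In all 1393 genes passed, 644 higher and 749 lower, 759 without cHF+R replicate 1 and 1702 with the slide as a block, but only 52 with median centring and 74 with scaling between arrays. The share of higher calls was 46.2%, but 13.5% with median centring, 28.4% with scaling between arrays and 58.5% in the deposited value table.

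The phospholipid effect ran in parallel without and with rosiglitazone. Over the 19465 genes the log2 changes of cHF+PC over cHF and of cHF+PC+R over cHF+R, which share no liver, had Pearson's r = 0.671 and Spearman's rho = 0.53, and genes are not independent replicates. When livers were resampled within groups, Pearson's r lay mostly between 0.418 and 0.648, below the value from the livers as they are. Drawing livers with replacement adds noise to the group means, so this range is not an interval for 0.671. Krt23, Igfbp2, Cyp2a4, Cyp4a10 and Sqle were among 335 genes that passed in both, 147 higher and 188 lower, where independent lists would share 27.6. None had opposite signs (0 genes), and 734 of the 766 genes that passed without rosiglitazone (95.8%) had the same sign with it.

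**Figure D3:**
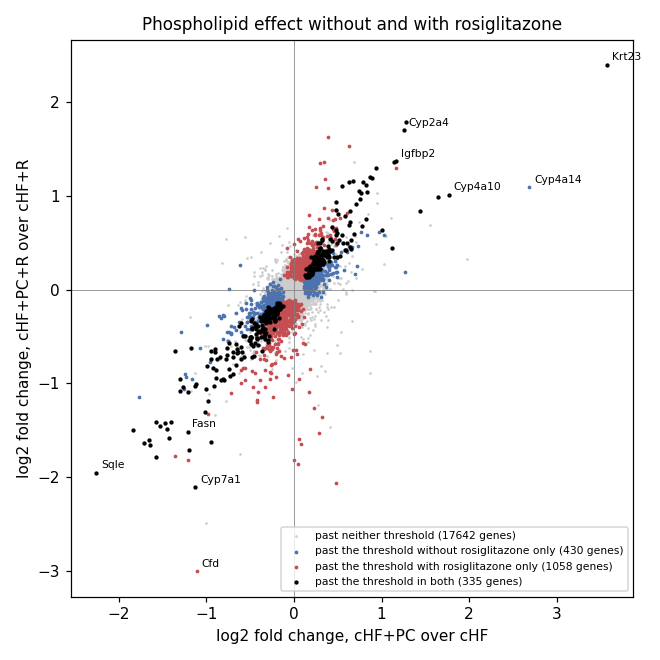
Log2 change of cHF+PC over cHF (x axis) against that of cHF+PC+R over cHF+R (y axis), 1 point per gene, coloured by the tests passed. The 335 genes past the threshold in both, such as Krt23 and Sqle, lie in the quadrants of equal sign.

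The fifth comparison, cHF+PC+R with cHF+PC, gave the rosiglitazone effect in livers that received phospholipids, and few genes passed. Plin4 rose by 2.18 ± 0.344 (adjusted p = 0.00262), Gprc5b by 1.69 ± 0.276 (adjusted p = 0.00345) and Lpl by 1.06 ± 0.194 (adjusted p = 0.0142), each in 8 of 8 slides. Rcan2, a regulator of calcineurin, rose by 0.79 ± 0.142, and Agmat fell by 0.31 ± 0.05. Cidec at 2.06 (adjusted p = 0.0488), Cd36 at 1.05 (0.0359) and Serpinb1a at 1.49 (0.0329) passed with all arrays. Each was lost without several single arrays, with the highest adjusted p for Cidec (0.146) and Cd36 (0.118) without cHF+PC+R replicate 3 and for Serpinb1a (0.0981) without cHF+PC+R replicate 6. The other probe of Cidec had a change of 0.79. Of 16 PPAR-gamma targets and lipid droplet genes 4 rose (4 adjusted over the list alone), with a median of 0.27, higher in 7 of 8 slides (camera adjusted p = 2.29e-06, and 0.461 with an estimated correlation). Peroxisomal and microsomal oxidation had a median of 0.30 and 10 genes higher adjusted over the list alone, though none over all genes, where Acaa1b had a change of 0.57 (limma adjusted p = 0.128). Its camera call (adjusted p = 6.34e-08) was lost with an estimated correlation (adjusted p = 0.461). Male-biased liver genes had a median of -0.26 and 2 genes lower adjusted over the list alone (camera adjusted p = 0.000345, and 0.461 with an estimated correlation). Stellate cell and fibroblast markers had a median of 0.14, higher in 6 of 8 slides, and 0 of 12 past the limma threshold (0 adjusted over the list alone). Their camera call (adjusted p = 0.00625) was lost with an estimated correlation (adjusted p = 0.715) and without cHF+PC replicate 5 (0.0516) or cHF+PC+R replicate 2 (0.137) or 7 (0.0522). Cholesterol synthesis had 0 of 19 enzymes past the limma threshold, with a median of -0.06 (camera adjusted p = 0.517), and Fasn a change of 0.01 ± 0.262.

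In all 26 genes passed in cHF+PC+R over cHF+PC, 23 higher and 3 lower, against 606 without phospholipids, and 1660 had an unadjusted p under 0.05. The 26 were all among the 606, and 560 of the 606 (92.4%) had the same sign with phospholipids. The count was 40 without cHF+PC replicate 2, 16, 15 and 17 without cHF+PC replicates 3, 6 and 7, and 56, 13, 16, 46, 14 and 14 without cHF+PC+R replicates 2, 3, 4, 5, 6 and 8. It was 31 with the slide as a block, 2 with median centring and 5 with scaling between arrays, and the share of higher calls of 88.5% became 77% in the deposited value table, 64.9% with array weights and 100% with median centring, scaling between arrays or only the compared groups in the fit.

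The interaction term tested whether the phospholipid effect differed with rosiglitazone, or the reverse. By limma 0 genes passed, 1292 had an unadjusted p under 0.05 (973 by chance), and the smallest adjusted p was 0.154. The limma count was 4 without cHF+PC+R replicate 6 and 3 with array weights. The genes with the smallest p were Fabp5l2 (-1.81 ± 0.361), Cyp2c37 (1.05 ± 0.212), Tlcd5 (-0.47 ± 0.096), Smcp (-0.72 ± 0.149) and Fabp5 (-1.65 ± 0.344). Cyp2c37, lower with rosiglitazone alone, had a change of -0.12 with it in the presence of the phospholipids, and Ehhadh an interaction of -0.67 (adjusted p = 0.303). Bile acid genes had a median interaction of 0.18 that held with an estimated correlation (camera adjusted p = 0.00322 and 0.04). With median centring it turned to -0.03 and the call was lost (camera adjusted p = 0.698). On simulated data at these arrays the term recovered 38.8% of true changes of 0.3, 85.1% of 0.6 and 98.5% of 1 on the log2 scale, while 4 unchanged genes also passed. Those changes were placed in genes drawn at random, and the median SE of the term over all genes was 0.0831. The rates do not carry over to genes of larger SE, such as Cyp2c37 (0.212), so 0 calls leave interactions of such genes open.

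Averaged over both rosiglitazone levels, the phospholipid effect reached 3166 genes, 1479 higher and 1687 lower, but only 164 with median centring and 1250 with scaling between arrays. Cholesterol synthesis had 18 enzymes lower (median -0.73, camera adjusted p = 0.0564 with an estimated correlation), fatty acid synthesis 13 genes lower (median -0.81, adjusted p = 0.0491 with an estimated correlation) and xenobiotic metabolism 15 genes higher (median 0.50, adjusted p = 0.00181 with an estimated correlation). Averaged over both phospholipid levels, the rosiglitazone effect reached 823 genes, 519 higher and 304 lower, but only 129 with median centring and 244 with scaling between arrays. Peroxisomal and microsomal oxidation had 13 genes higher (median 0.47, adjusted p = 0.0463 with an estimated correlation) and the PPAR-gamma list 8 (median 0.44, adjusted p = 0.161 with an estimated correlation). The shares of higher calls were 46.7% and 63.1%. With median centring they were 23.8% and 93.0%, with scaling between arrays the rosiglitazone share was 75.8%, and in the deposited value table it was 33.4%.

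Other lists passed camera on the averages at the preset correlation. For the phospholipid average they were PPAR-gamma targets (median -0.53, adjusted p = 0.348 with an estimated correlation), mitochondrial oxidation (0.13, 0.348), triglyceride synthesis (-0.20, 0.317), cell cycle (-0.12, 0.504) and bile acid genes (0.14, 0.0817). Peroxisomal oxidation (0.12, 0.348) turned to -0.014 with scaling between arrays. Circadian clock genes (0.26, 0.142) were lost without cHF+R replicate 6 (0.05), and adipocyte markers (-0.45, 0.348) without cHF+R replicate 3 (0.0604) or cHF+PC+R replicate 2 (0.0523). For the rosiglitazone average they were male-biased genes (-0.23, 0.327), fatty acid synthesis (0.17, 0.539), stellate cell markers (0.15, 0.494) and bile acid genes (-0.11, 0.0174). The bile acid median turned to 0.09 with median centring, where the camera call was lost (adjusted p = 0.305). Cholesterol synthesis (-0.09, 0.764) turned to 0.06 with median centring and 0.17 with scaling between arrays, and was lost without any 1 of 10 arrays (highest 0.167, without cHF+PC replicate 4). Hepatocyte markers (-0.06, 0.494) turned to 0.13 with median centring and were lost without cHF+R replicate 5 (0.101), cHF+PC replicate 6 (0.0718) or cHF+PC+R replicate 6 (0.0629). Cell cycle genes (0.11, 0.689) were lost without cHF replicate 1 (0.0544), cHF+R replicate 2 (0.0501) or cHF+PC+R replicate 6 (0.0659), and erythroid markers (-0.05, 0.307) without cHF+R replicate 1 (0.0515). Macrophage and Kupffer cell markers (0.10, 0.689) were lost without any 1 of 13 arrays (highest 0.328, without cHF+R replicate 6).

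Markers of other cell types and further pathways gave few calls. In cHF+PC against cHF and in cHF+R against cHF, limma passed 0 of 15 macrophage and Kupffer cell markers (1 fell with rosiglitazone adjusted over the list alone), 0 of 11 lymphocyte markers, 0 of 6 cholangiocyte markers, 0 of 7 MHC class II genes and 0 of 4 exocrine pancreas markers. Their medians with phospholipids were -0.07, 0.06, 0.00, 0.15 and -0.06, and with rosiglitazone 0.16, 0.07, -0.02, 0.19 and -0.02. Stellate cell and fibroblast markers had 1 of 12 lower with phospholipids (1 adjusted over the list alone) and 0 past limma with rosiglitazone (1 rose adjusted over the list alone), where the camera adjusted p of 0.0382 became 0.638 with an estimated correlation and was lost without any 1 of 6 arrays (highest 0.221, without cHF+R replicate 1). Hepatocyte markers had 1 of 11 lower with phospholipids (3 rose and 1 fell adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.667). Of the 4 measured adipocyte markers 1 fell with phospholipids (1 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.252). It was Car3, a carbonic anhydrase, at -0.75, a call lost without any 1 of 6 arrays (highest adjusted p = 0.0688, without cHF+PC replicate 4). Endothelial markers had 1 of 12 lower with phospholipids, and of 3 erythroid markers Alas2 fell by 0.42 with rosiglitazone (1 each adjusted over the list alone). Interferon-stimulated genes had 1 of 17 lower in each comparison (1 each adjusted over the list alone), and their camera adjusted p = 0.0488 with phospholipids became 0.727 with an estimated correlation and 0.066 with the slide as a block, and was lost without any 1 of 14 arrays (highest 0.254, without cHF replicate 3). The unfolded protein and amino acid stress genes rose in 2 of 14 cases with phospholipids, where Dnajb9 rose by 0.61 (0.25 at its other probe), and in 1 with rosiglitazone (3 and 1 adjusted over the list alone). Their camera adjusted p values of 0.0488 and 0.0267 became 0.635 and 0.494 with an estimated correlation. The call with phospholipids, a median of 0.05 that turned to -0.02 with scaling between arrays, was lost without any 1 of 14 arrays (highest 0.16, without cHF replicate 3), and that with rosiglitazone without cHF replicate 3 (0.0721) or cHF+R replicate 4 (0.0904) or 6 (0.163). Cell cycle genes had 1 of 14 lower with phospholipids and 0 past limma with rosiglitazone (1 and 0 adjusted over the list alone), where the camera adjusted p of 0.00655 became 0.616 with an estimated correlation. Acute phase proteins had 0 and 1 of 18 past limma (0 and 1 adjusted over the list alone), and respiratory chain genes 1 and 0 of 18 (1 and 0 adjusted over the list alone). Antioxidant and metallothionein genes had 0 of 9 past limma in both. Of 17 genes of glucose metabolism and insulin signalling, 1 rose and 1 fell with phospholipids and 1 fell with rosiglitazone (2 rose and 3 fell, and 1 fell, adjusted over the list alone). Of 17 genes of phospholipid, choline and methionine metabolism, 1 fell with phospholipids (1 adjusted over the list alone) and 0 passed limma with rosiglitazone (3 rose and 1 fell adjusted over the list alone). Of 12 genes of sterol uptake and SREBP-2 regulation, 1 rose and 1 fell with phospholipids (1 and 2 adjusted over the list alone). Immediate early genes had 1 of 9 higher and 1 lower with phospholipids (2 and 1 adjusted over the list alone) and 0 past limma with rosiglitazone. Circadian clock genes had 1 of 13 higher with phospholipids (1 adjusted over the list alone) and 0 with rosiglitazone (1 fell adjusted over the list alone). Over all genes, 3591 had an unadjusted p under 0.05 with phospholipids and 2905 with rosiglitazone.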

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

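The test for adipose tissue and the splits of single list medians were chosen after the results were seen, and the clock score was built after the changes of the clock genes were seen.

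Cfd, Cidea, Cidec and Plin4, genes best known from fat cells, were higher in cHF+R than in cHF. The median Cy5 intensity went from 2170 to 60900 for Cfd and from 1330 to 27700 for Cidea, whose log2 change was 3.28 ± 0.949 (adjusted p = 0.0529). Plin1 (well above background on 1 of 6 cHF+R arrays), Adipoq and Lep (0) were near background in every group. Low values of these adipocyte markers would go against adipose tissue in the samples. A probe that is dim in every group is not known to detect its transcript, however. Adipose tissue and a response of liver cells thus cannot be told apart. Adig, another gene of fat cells, went from 98.6 to 476, a change of 1.61 (adjusted p = 0.0728), though at its other probe the mean log2 ratio went only from -0.075 to 0.228, and Retn from 137 to 264 and from 68.3 to 206 at its other probe. No single cHF+R liver carries the pattern, since without any 1 of them the lowest change of the 4 genes was 2.17 (Plin4).

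Fewer genes passed for rosiglitazone with phospholipids than without them, 26 against 606. Genes chosen by their chance values would shrink in any second look, so 200 genes were chosen on part of the cHF and cHF+R arrays, in 50 divisions. In the arrays left out their median change was 0.621, against 0.316 with phospholipids, a difference of 0.301 or 2.81 SE. These genes were chosen for their response without phospholipids, and no genes were chosen on cHF+PC and cHF+PC+R arrays in turn. The difference therefore holds for such genes and does not show a smaller response of all genes. The comparison with phospholipids held more arrays (8 and 8, against 7 and 6), with a median SE of 0.0556 against 0.0618. A damped response may remain as a hypothesis, and no single gene passed the interaction test (0 by limma, 1292 at an unadjusted p under 0.05).

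Cholesterol synthesis enzymes were lower with phospholipids. Livers taken at another circadian phase could give this. With a clock score of each liver as a covariate the median change in cHF+PC over cHF was -0.83, against -0.75 without it, and 17 of 19 enzymes still passed. The mean score was -0.261 in cHF (SD 0.43) and 0.484 in cHF+PC (SD 1.169). With rosiglitazone it was -0.622 in cHF+R (SD 0.583) and 0.211 in cHF+PC+R (SD 0.515), so the score was higher with phospholipids at both levels. A linear score built after its genes' changes were seen may miss a shift of phase, so a difference in phase is not excluded. One array of high detection, cHF replicate 4, does not carry the lower enzymes, since without any 1 array the highest median was -0.65 (without cHF+PC replicate 2) and without cHF replicate 4 it was -0.73. A response to the diet may remain as a hypothesis; food intake was not tested.

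Other splits of the arrays tested chance. For cHF+PC, cHF+R and cHF+PC+R against cHF, 1 of 100 splits, the real one, gave as many genes as 766, 606 and 1849, with 43, 151 and 226 as the highest others. The same held for cHF+PC+R over cHF+R (1393 against 123), for cHF+PC+R over cHF+PC (26 against 6), for both averaged effects (3166 against 162 and 823 against 8) and for the correlation of the phospholipid effects (0.671 against 0.494). No other split matched these values, and 1 of 100 is the lowest share that such splits can show. The count of 26 was also unstable, with a median of 3 (0 to 29) at 6 arrays per group. For the interaction, where 0 genes passed limma (1292 at an unadjusted p under 0.05), 100 of 100 splits match that count by definition (highest other 1), so the splits test nothing there.

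Chance cannot be excluded for the number of lists that passed camera at the preset correlation. In the order above, 9, 24, 27, 30 and 86 of 100 splits gave as many lists as the real 9, 11, 8, 11 and 4, with 12, 20, 11, 20 and 15 as the highest others. It was 63 for the 6 interaction lists (highest other 12), and 14 and 15 for the 11 lists of each averaged effect (highest others 14 and 15). The median over the other splits was 4, 7, 5, 9 and 7 lists for the first 5 comparisons, 7 for the interaction and 6 for each average. Of the other splits, 92 to 99 per comparison passed at least 1 list. Random regroupings thus often passed lists at the preset correlation, and its adjusted p-values should be read with that in mind. The interaction splits shuffled livers over all 4 groups, so they carry effects of the single supplements and do not test the interaction alone. Of 30 lists, 10 with phospholipids and 5 with rosiglitazone, each against cHF, had a median that fewer than 5 of 100 splits matched, where chance gives 1.2. The cholesterol, fatty acid synthesis and xenobiotic medians with phospholipids and the bile acid median with rosiglitazone were each matched by 1, the real split, though other splits came close. The largest others in size were 0.737 for cholesterol (real -0.75), 0.638 for fatty acid synthesis (-0.71), 0.35 for xenobiotic metabolism (0.39) and 0.136 for bile acid genes (-0.18). With phospholipids the triglyceride and VLDL, mitochondrial and hepatocyte medians were also matched by 1 (largest others 0.137, 0.135 and 0.154, real -0.17, 0.16 and 0.16), the adipocyte median by 2, the peroxisomal by 3, the PPAR-gamma by 13, the interferon by 40 and the unfolded protein by 53. With rosiglitazone the stellate cell median was matched by 2, the peroxisomal by 3, the adipocyte by 4, the PPAR-gamma and hepatocyte by 6, and the cell cycle and cholesterol by 7. The unfolded protein, male-biased and fatty acid synthesis medians were matched by 15, 28 and 30.

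Of 375 sets of values within a group, 29 held a liver far from the others of its group, where chance flags about 1 in 20, or 18.8. On cHF replicate 4 80.8% of spots were above background and the signal was 5.18 times the background. The list medians apart were mitochondrial oxidation in cHF+PC replicate 6 (-0.26) and cHF+PC+R replicate 2 (-0.21), and PPAR-gamma targets in cHF+R replicate 6 (-0.36). Interferon-stimulated genes were high in cHF replicate 3 (0.47) and cHF+PC+R replicate 2 (0.40), adipocyte markers in cHF+PC+R replicate 6 (0.79) and antioxidant genes in cHF+PC replicate 2 (0.14). In cHF+R replicate 6 the log2 ratio was 1.51 for Lpl, -1.05 for Aatk, -0.68 for Acacb, -1.31 for Grin3b and -0.57 for Agmat. In cHF replicate 1 it was -1.68 for Cyp2a21-ps, -1.66 for Cyp2a4, -0.086 for Igfbp2 and -1.73 for Cd36. In cHF replicate 7 it was -0.63 for Gprc5b and -0.69 for Otop1. In cHF+PC+R replicate 4 it was 2.43 for Cyp4a14, 1.26 for Cyp4a32 and -1.71 for Ces2b. The remaining livers were cHF+PC+R replicate 2 (-2.75 for Aatk) and 6 (-0.15 for Igfbp2), cHF+R replicate 1 (-1.19 for Tnfaip8l1), and cHF+PC replicates 2 (-1.11 for Grin3b, -2.25 for Rad51b) and 6 (-0.99 for Tnfaip8l1).

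The effect of one supplement differed with the other in 6 lists by camera on the interaction. The medians were -0.28 for peroxisomal and microsomal oxidation, 0.18 for bile acid genes (-0.03 with median centring), 0.10 for xenobiotic metabolism (-0.12 with median centring, -0.011 with Cy5 alone), 0.13 for hepatocyte markers (-0.12 with median centring, -0.012 with scaling between arrays), -0.057 for the respiratory chain and -0.23 for PPAR-gamma targets. The hepatocyte call was lost without cHF+R replicate 5 (adjusted p = 0.0583) or cHF+PC+R replicate 2 (0.0876). The respiratory chain call was lost without any 1 of 6 arrays (highest 0.342, without cHF+R replicate 1) and the PPAR-gamma call without any 1 of 11 (highest 0.291, without cHF+PC+R replicate 2). With an estimated correlation the bile acid list alone passed (adjusted p = 0.04), and with median centring its camera call was lost (0.698). Of 100 splits, 2 matched its median, against 20 for the peroxisomal list, 54 for xenobiotic metabolism, 20 for hepatocyte markers, 30 for the respiratory chain and 50 for PPAR-gamma targets. Of 30 lists 1 had fewer than 5, where chance gives 1.2. These splits shuffled the livers over all 4 groups, so effects of the single supplements also enter them. They cannot decide on the interaction alone, and chance was not excluded.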

How the results depend on the processing

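Leaving out each array for the lists, equal numbers of arrays and the splits of list medians were chosen after seeing the data. For every change named below the cause was not tested, except for the fewer arrays of the equal draws. Median centring in place of loess and scaling after loess lowered most counts. In the order cHF+PC, cHF+R and cHF+PC+R against cHF, cHF+PC+R against cHF+R and against cHF+PC, phospholipid average and rosiglitazone average, median centring gave 10, 82, 77, 52, 2, 164 and 129 genes. Scaling between arrays gave 255, 70, 144, 74, 5, 1250 and 244. Of 483 gene results, 288 weakened with median centring and 283 with scaling. Cy5 alone gave 390, 302, 767, 658, 39, 1861 and 451, and r = 0.552 for the phospholipid effects. Array weights gave 1223 (cHF+PC), 148 (cHF+PC+R over cHF+PC), 3 (interaction) and 1313 (rosiglitazone average). No background subtraction gave 1192 (cHF+PC) and 81 (cHF+PC+R over cHF+PC). For cHF+PC+R over cHF+PC, processed signals gave 63 and the deposited values 61. In the order above, 6 arrays per group gave medians of 435.5 (177 to 702), 527 (401 to 631), 1175.5 (756 to 1869), 1053 (597 to 1765), 3 (0 to 29), 2510.5 (1698 to 3132) and 538 (440 to 737), so cHF+PC no longer exceeds cHF+R, and 0 to 8 for the interaction. With only the compared groups 777 (cHF+PC+R over cHF+R) and 11 (cHF+PC+R over cHF+PC) passed. Directions turned with median centring for Abcb4 with rosiglitazone (0.021), Etfb in cHF+PC+R over cHF+R (-0.11) and in the averages (-0.035 and 0.026), Amacr in the rosiglitazone average (0.058), mitochondrial oxidation in cHF+PC+R over cHF+R (-0.10), triglyceride synthesis in cHF+PC+R over cHF (0.04), hepatocyte markers in the interaction (-0.12) and, in the rosiglitazone average, bile acid (0.09), hepatocyte (0.13) and cholesterol (0.06) lists. With scaling they turned for Apoc3 in cHF+PC over cHF (0.11), cholesterol synthesis in the rosiglitazone average (0.17), hepatocyte markers in the interaction (-0.012) and peroxisomal oxidation in the phospholipid average (-0.014). For PPAR-gamma targets in the interaction camera's direction turned but the median kept its sign (-0.013). Camera sets a list against the other genes. Of 71 list calls, 17 weakened and 2 reversed in camera's direction with median centring, and as many with scaling. A turned list median therefore need not mean that the list changed sides against the other genes. The bile acid camera calls whose medians turned were nevertheless lost with median centring. Of 71 list calls over all comparisons, 15 passed with an estimated correlation and 37 by fry, which passed 42 lists in all. Without 1 array the counts ranged from 439 to 872, 445 to 685, 1383 to 2031, 759 to 1976, 13 to 56, 2634 to 3525 and 670 to 1043, 0 to 4 for the interaction (4 without cHF+PC+R replicate 6), 66 to 80 for list calls and 0.643 to 0.682 for r. By replicate number, the median r between paired livers ran from -0.064 to 0.087 over 5 comparisons (highest pair 0.4), and in cHF+PC and cHF+PC+R, where the number is the slide, 4 of 8 pairs lay above 0.1; a replicate block gave 881, 586, 1941, 1408, 21, 3226 and 790 genes. The slide as a random block was not run for the lists, since camera takes no such block. Signal over background, 2.69 to 3.78 on all but cHF replicate 4, limits what dim probes can show.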

Other observations

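The clock score was built, and the splits of list medians were chosen, after the changes of the clock genes were seen, and the members of lists named here follow the rule for named genes.

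Pklr and Lrat, of other lists, moved with the phospholipids without and with rosiglitazone. Pklr, the liver pyruvate kinase, fell by 0.80 in cHF+PC over cHF and by 0.96 in cHF+PC+R over cHF+R, and by 1.34 in cHF+PC+R over cHF. Lrat, which esterifies retinol and is a marker of stellate cells, fell by 0.49, 0.58 and 0.34 in the same comparisons, while 0 other stellate cell markers passed limma in any of them. Oasl1, an interferon-stimulated gene, fell by 0.68 in cHF+PC and by 0.72 in cHF+PC+R against cHF, with 0 of the other listed interferon genes past the limma threshold there, and had a change of -0.40 in cHF+PC+R over cHF+R (adjusted p = 0.111). Ttr, transthyretin, fell by 0.51 and 0.59 in those comparisons and had -0.28 in cHF+PC+R over cHF+R (adjusted p = 0.118). Cps1, of the urea cycle, rose by 0.53 in cHF+PC+R over cHF, with 0.43 in cHF+PC over cHF (adjusted p = 0.0843). In cHF+PC+R over cHF+R Cps1 rose by 0.56 (adjusted p = 0.019), a call lost without cHF+R replicate 1 (0.0705) or 5 (0.0512).

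Apcs, serum amyloid P, rose by 1.15 with rosiglitazone alone (adjusted p = 0.000326) and fell by 1.19 in cHF+PC+R over cHF+R (adjusted p = 0.000114). Its interaction was -0.78 (adjusted p = 0.604), and it was the only acute phase gene of 18 to pass with rosiglitazone. Cyp2d9, a male-biased cytochrome, went the other way, with -0.65 and 0.60 in the same comparisons and an interaction of 0.36 (adjusted p = 0.648). For Apcs and Cyp2d9 both comparisons use the same cHF+R livers, so a chance deviation of that group alone would give both changes. Mat1a, which makes the methyl donor S-adenosylmethionine, rose by 0.59 in cHF+PC+R over cHF+R.

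The clock list passed camera in cHF+PC+R over cHF+R, with a median of 0.34 that only the real 1 of 100 splits matched, the largest other being 0.198 (adjusted p = 0.0253, and 0.136 with an estimated correlation; 0.0822 without cHF+R replicate 6). In cHF+PC over cHF its median was 0.21, matched by 5 splits (camera adjusted p = 0.111). Of the 13 measured clock genes, Cry2 rose by 0.29 in cHF+PC over cHF (adjusted p = 0.0462) and by 0.41 in cHF+PC+R over cHF+R (adjusted p = 0.00256), where its other probe had a change of 0.12. Its call in cHF+PC over cHF was lost without any 1 of 14 arrays (highest adjusted p = 0.12, without cHF+PC replicate 4). Tef rose by 0.83 in cHF+PC+R over cHF+R (adjusted p = 0.0403), a call lost without any 1 of 9 arrays (highest adjusted p = 0.0999, without cHF+R replicate 1). The clock score takes 11 of these genes, signed by the arm of the clock they belong to, and leaves out Cry2 and Cry1, which were given no arm. In both comparisons 11 of the 11 moved in the direction of their arm. Arntl, Clock and Nfil3, of the arm with negative sign, were lower (-0.535, -0.105 and -0.355 in cHF+PC over cHF). In cHF+PC+R over cHF+R they had -0.551, -0.066 and -0.391. The list median thus mixes changes of both signs. Since the 11 were picked with their changes in view, no test of the score itself is given. The time of day at which the livers were taken may differ between the groups or the diets may shift the clock, and the labels used here give no times. With the score as a covariate the cholesterol synthesis enzymes had a median change of -0.83 in cHF+PC over cHF, which does not exclude a difference in phase.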
